A study of Rattus norvegicus with 6 samples.

How the data were processed

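Messenger RNA of regenerated rat sciatic nerve was measured in 6 libraries, 3 of the NC group and 3 with the GDNF-Gel/HA-Mg conduit. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads and libraries were made with a NEBNext Ultra RNA kit. This kit does not mark the strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The submitters' processing notes name Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2, with no role for each. The genome build and the annotation are not given in the sources used here.

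The authors deposited a table of estimated counts (expected counts) per gene, made by a counter not given in the sources used here and not normalized as far as its column totals show. It has 1898 to 2085 genes per library at values that are not whole, for 23091 genes. These were rounded to whole numbers before testing. Symbols and Ensembl identifiers were taken from the table itself, 720 genes had no symbol, and no coordinates were used. Columns were matched to samples by name. The treated columns are named Gel_HA-Mg without GDNF and were assigned to the GDNF-Gel/HA-Mg group, the only group of the series with that material. Groups came from the sample titles. Library pairs were compared by chi-square of their counts, and no pair agreed within sampling noise.

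Genes were filtered with filterByExpr, which left 13999, and scaled by TMM. The groups were compared with edgeR 4.0.16 (quasi-likelihood test, two-sided, group as the only term) under R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error was the log2 fold change divided by the root of the F statistic, and 95% intervals from it are approximate. CPM values use the TMM-scaled library size. The biological coefficient of variation was 0.384. Shares of counts have 95% intervals at most 0.0401 percentage points wide, which cover counting error only.

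Gene lists were fixed before the data were examined, 37 in number with 823 symbols, of which 772 were in the table. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 37 lists. Camera was repeated with an estimated correlation, and fry was run beside it. Camera compares a list with all other genes, while fry asks if the genes of a list move one way on balance. Where a symbol had several entries, the one with the highest total was used. Gfra1 was not analysed here.

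The rule for genes to be named was also fixed before the data were examined. It took called genes with a mean log2 CPM of at least 2, a symbol that is not provisional and no overlap between the groups. As no gene was called, it took the 5 genes per direction with the smallest unadjusted p that met the other conditions, a reading of the rule made after the result was known. It added up to 3 members per list by smallest unadjusted p, and a fixed set of markers that includes Gdnf, Ret, Jun, Ngfr, Sox10 and Mbp. Some genes that this rule took are not reported here. Mmp7 is named as a list member. Acaca and the other list examples come from the same rule, and the DESeq2 calls outside it were named after their values were seen.

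The gene test was tested on simulated counts drawn from the means and library sizes of this comparison. Each gene was drawn independently, so variation shared by many genes of a library was not simulated. At the dispersion estimated from these libraries, over 13811 genes, it recovered 0 of 50 genes changed 2-fold, 30 of 49 changed 4-fold, 37 of 48 changed 8-fold and 46 of 50 changed 16-fold, with 3 false calls among 116. Alternatives were other scalings (RLE, upper quartile, TMM without the 50 most abundant genes), DESeq2 1.42.0, limma-voom, no filter, a filter of CPM of at least 1 in at least 3 libraries, an added log2 fold threshold of 1, the replicate number as a block, and each library left out in turn. Haemoglobin level as a covariate, and leaving out haemoglobin, muscle and adipocyte genes, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.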

Results

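Messenger RNA was sequenced from sciatic nerve that had regenerated after a nerve defect in male Sprague-Dawley rats. In the control group (NC, 3 libraries) the wound was closed without an implant. In the treated group (3 libraries, called implant 1 to implant 3 here) the defect received GDNF-Gel/HA-Mg, a nerve conduit that carries glial cell line-derived neurotrophic factor (GDNF). The total count was 16421669, 15897850 and 17990057 in NC 1, NC 2 and NC 3, and 16120518, 18491379 and 17619224 in implant 1, implant 2 and implant 3. The labels do not give the time after surgery. They also do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may not be that between animals. The level of the myelin list spanned 26.2-fold from NC 1 to NC 2, which argues against repeat libraries of 1 RNA sample for this pair.

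The comparison asked how the conduit altered gene expression in the regenerating nerve. No gene passed edgeR's test over all genes, while DESeq2 called 11. Described first are 4 of the genes that the naming rule took, which are not the 4 with the smallest unadjusted p. Of these, DESeq2 called Olr1, Fmod and Crispld2 but not Myo1f. On the higher side, Myo1f, a myosin of leukocytes, averaged 33.8 ± 1.38 CPM (counts scaled to library size; mean ± SD, n = 3) in NC and 47.5 ± 2.49 (n = 3) with the conduit. Olr1, a receptor for oxidised low-density lipoprotein, averaged 8.14 ± 1.27 CPM in NC and 25.7 ± 11.2 with the conduit. On the lower side, fibromodulin (Fmod), a small proteoglycan that binds collagen, averaged 99.3 ± 17.8 CPM in NC and 48.2 ± 6.61 with the conduit. Crispld2 averaged 144 ± 18.9 CPM in NC and 84.1 ± 6.42 with the conduit.

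The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 13999 genes higher and 0 lower with the conduit. At an unadjusted p under 0.05 it found 241 genes, 144 higher and 97 lower, where about 700 would fall by chance alone. The smallest adjusted p was 1.0. DESeq2 called 11 of these 13999 genes, 5 higher and 6 lower, and limma-voom called 0. In 5.69% of the genes the 3 libraries of one group all lay above those of the other, against 10% by chance. The median standard error of the log2 fold change was 0.23, and the 95% interval excluded a 4-fold change for 88.3% of the genes.

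Among genes with a mean log2 CPM of at least 2, a symbol that is not provisional and no overlap between the groups, the 5 with the smallest unadjusted p on the higher side were Znf431 (ENSRNOG00000067344), Ccdc88b (ENSRNOG00000024931), Myo1f (ENSRNOG00000008409), Olr1 (ENSRNOG00000056219) and Clec4a1 (ENSRNOG00000042139). Their log2 fold changes were 1.25 ± 0.20 (SE), 0.85 ± 0.16, 0.49 ± 0.10, 1.66 ± 0.35 and 0.52 ± 0.11. Znf431 is uncertain, because its symbol covers 63 entries of the table and near-identical copies can share reads. By the same conditions, the 5 on the lower side were Bcar3 (ENSRNOG00000013737), Fmod (ENSRNOG00000003183), Crispld2 (ENSRNOG00000016752), the aggrecan-cleaving protease Adamts5 (ENSRNOG00000057794) and Pamr1 (ENSRNOG00000005348). Their log2 fold changes were -0.87 ± 0.15, -1.04 ± 0.18, -0.78 ± 0.14, -0.57 ± 0.13 and -0.87 ± 0.21. DESeq2 called Znf431, Ccdc88b, Olr1, Bcar3, Fmod and Crispld2 among its 11, with adjusted p of 0.00137, 0.0476, 0.0353, 0.0144, 0.00665 and 0.00601. Its other named genes were Slfn4, Mmp7 and the provisional AC135826.1 and AABR07072096.1, and the last had no symbol.

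Mmp7 (matrilysin, ENSRNOG00000010507) had 20, 40 and 15 counts in the NC libraries and 0, 0 and 1 in the implant libraries. Its summed level was 78.1 times as high in NC, with a 95% counting interval of 13.6 to 3124, which leaves out the spread between samples. Adjusted over the list alone, Mmp7 passed among 23 matrix proteases and inhibitors (edgeR adjusted p 0.0181) and Fmod among 27 fibroblast and fibrous matrix genes (edgeR adjusted p 0.0333). These 2 genes were the only members of the 37 lists to do so, and neither passed over all genes in edgeR, while DESeq2 called both over all genes (adjusted p 0.0174 for Mmp7 and 0.00665 for Fmod). Each list was adjusted separately with no correction over the 37 lists. A few passes can therefore arise by chance, and the 2 within-list passes do not single these genes out.

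**Figure D1:**
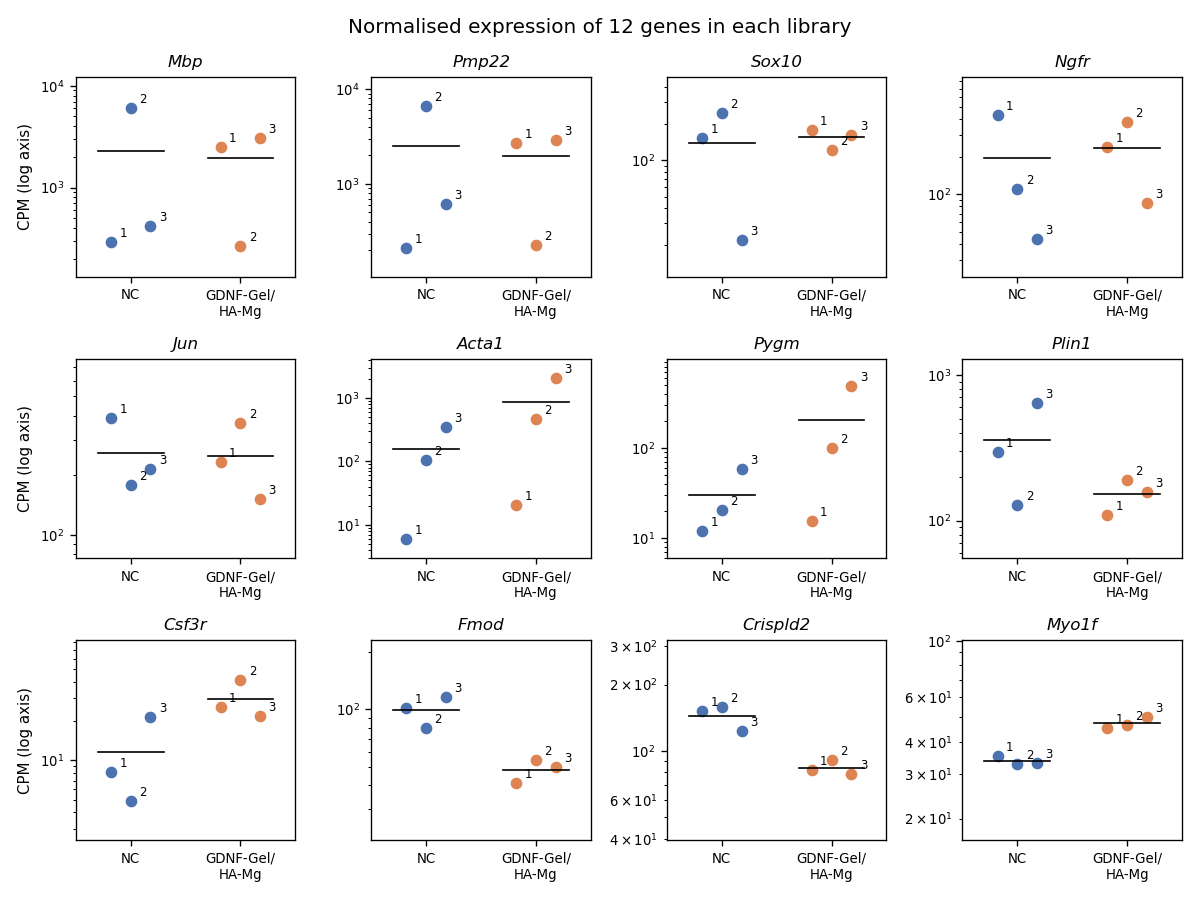
Normalised expression (CPM, log axis) of 12 genes in each library of the NC and GDNF-Gel/HA-Mg groups; each point is 1 library with its number, and the line is the group mean. Fmod and Crispld2 are lower and Myo1f is higher in all 3 implant libraries, as the rule that took them required. Over all tested genes, 5.69% had no overlap between the groups, against 10% by chance. Mbp ranges from 295 to 6100 CPM within NC.

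The transcripts of GDNF signalling did not separate the groups. Gdnf itself had 27, 1 and 2 counts in NC and 9, 16 and 1 with the conduit, too few to be tested. Ret, its signalling receptor, averaged 2.43 ± 1.42 CPM in NC and 2.90 ± 1.64 with the conduit. In the list of GDNF family signalling, 11 of 17 tested genes had a positive log2 fold change, with a median of 0.15 (camera adjusted p 0.307). Etv4, a transcription factor induced by this pathway, averaged 3.02 ± 2.53 CPM in NC and 6.54 ± 2.37 with the conduit. The neurotrophins and other trophic factors had a median of 0.08 (camera adjusted p 0.733). Among them Ntf3, which encodes neurotrophin-3, averaged 2.16 ± 0.43 CPM in NC and 1.22 ± 0.15 with the conduit. Lif averaged 4.61 ± 2.17 and 8.07 ± 3.74 CPM. Components of PI3K-AKT, MAPK and JAK-STAT signalling had a median of 0.01 (camera adjusted p 0.691).

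Myelin transcripts varied widely between the libraries of each group. Mbp, which encodes myelin basic protein, stood at 295, 6100 and 420 CPM in NC 1, NC 2 and NC 3. With the conduit it stood at 2526, 266 and 3085 CPM in implant 1, implant 2 and implant 3. Its group means were 2272 ± 3316 CPM in NC and 1959 ± 1492 with the conduit. Pmp22, another myelin gene, averaged 2513 ± 3648 and 1963 ± 1506 CPM. The level of the myelin list spanned 26.2-fold over the libraries, and its median log2 fold change was -0.11 (camera adjusted p 0.218). Sox10, the transcription factor of the Schwann lineage, stood at 154, 243 and 21.8 CPM in NC and at 179, 122 and 161 with the conduit. Ngfr, a marker of denervated Schwann cells, stood at 434, 109 and 43.7 CPM in NC and at 240, 380 and 84.8 with the conduit. S100b, another Schwann lineage marker, averaged 514 ± 271 CPM in NC and 294 ± 91.0 with the conduit. By library it stood at 219, 752 and 571 CPM in NC and at 361, 190 and 331 with the conduit. In NC 3, where Sox10 was lowest, S100b was thus not low. Jun, which drives the repair state of Schwann cells, averaged 261 ± 111 and 251 ± 108 CPM. The lists of repair Schwann cell genes (median 0.09, camera adjusted p 0.310), Schwann lineage identity (-0.02, 0.316) and non-myelinating Schwann cells (0.12, 0.231) were not called. This depended on single libraries. Of the myelin genes, 19 of 25 had a negative log2 fold change. Myelin changed direction without NC 1, NC 3, implant 1 or implant 3, and repair genes without NC 3, implant 1 or implant 2, none past the threshold. The runs that passed were on the higher side with the conduit. Myelin passed camera without NC 2 (1.5e-06) or implant 2 (5.3e-06), and lineage identity without NC 2 (0.0030) or implant 2 (0.0270). Repair genes passed without NC 1 (0.0044) or implant 3 (0.0027), and non-myelinating genes without NC 1 (0.0238). Each library left out in these passes was the highest NC or the lowest implant library of its list. Leaving it out moves the difference upward, so these passes do not back an effect of the conduit. They also used the preset correlation of 0.01, where the estimates for these 4 lists were 0.88, 0.47, 0.35 and 0.30. With estimated correlations and all 6 libraries, camera gave each an adjusted p of 0.872. With haemoglobin level as a covariate, chosen after seeing the data, these 4 lists passed on the higher side (0.0345, 0.000448, 0.00506 and 0.000147). Also not called by camera were neuronal and axonal transcripts (0.01, 0.908), axon growth and guidance (-0.03, 0.446), perineurial cells (0.30, 0.197) and basement membrane (0.00, 0.840). Axon growth passed on the higher side without NC 1 (0.0213). Perineurial genes passed without NC 2 (0.0021), without implant 2 (0.0324), with no filter on low counts (0.0414) and with the covariate (0.0247).

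Immune lists were 4 of the 8 lists called higher. Genes of neutrophils rose with the conduit as a set, with 11 of 13 positive and a median log2 fold change of 0.82 (camera adjusted p 0.000414 with the preset correlation, adjusted p = 0.872 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, averaged 11.6 ± 8.86 CPM in NC and 29.6 ± 10.4 with the conduit. T and NK cell genes rose as a set, with 17 of 18 positive and a median of 0.42 (0.000266, adjusted p = 0.872 with an estimated correlation), and Cd3g averaged 2.64 ± 0.79 and 4.78 ± 2.24 CPM. Monocyte and macrophage genes rose as a set by a small amount, with 21 of 25 positive and a median of 0.17 (0.00059, adjusted p = 0.872 with an estimated correlation). Their pan-leukocyte member Ptprc averaged 84.5 ± 12.5 and 107 ± 7.17 CPM. Genes of MHC class II presentation rose as a set, with 9 of 14 positive and a median of 0.19 (0.000946, adjusted p = 0.872 with an estimated correlation), and RT1-Ba averaged 15.3 ± 4.52 and 38.9 ± 20.7 CPM. None of these 4 calls held with an estimated correlation.

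Haemoglobin took 1.19%, 1.02% and 25.2% of the counts in NC 1, NC 2 and NC 3, and 8.08%, 12.9% and 14.8% in the implant libraries. The neutrophil list was lowest in NC 1 and NC 2. With haemoglobin level as a covariate, chosen after seeing the data, the adjusted p was 0.361 for neutrophils, 0.864 for T and NK cells and 0.462 for monocytes and macrophages, while MHC class II kept its call (5.3e-06). Leaving out 1 library also ended each call. Neutrophils lost it without NC 2 (0.058), and MHC class II without NC 3 (0.786). T and NK cells lost it without NC 2 (0.622) or implant 2 (0.132), and monocytes and macrophages without NC 1 (0.065), NC 2 (0.054) or implant 3 (0.117).

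Other immune lists were not called. They were inflammatory cytokines and mediators (median 0.11, camera adjusted p 0.0547), mast cells (-0.28, 0.0748), B and plasma cells (-0.01, 0.191), the interferon response (0.00, 0.191) and anti-inflammatory macrophage markers (0.02, 0.327). Inflammatory cytokines passed without NC 3 (2.3e-06), implant 2 (0.0390) or implant 3 (0.0023), with RLE scaling (0.0393) and with limma-voom values (0.0194). Mast cell genes passed on the lower side without NC 2 (0.0090), implant 1 (0.0354) or implant 2 (0.0014) and with the haemoglobin covariate (0.00933). On the higher side, B cell genes passed without NC 1 (0.0160) and anti-inflammatory markers without NC 3 (0.0029). The interferon response passed on that side without NC 1 (0.0044), NC 3 (0.0134) or implant 3 (0.000889). Among their members Nos2, the inducible nitric oxide synthase, averaged 3.27 ± 3.75 CPM in NC and 8.71 ± 2.23 with the conduit. Arg1 averaged 4.73 ± 0.97 and 6.57 ± 0.78 CPM. Cd68, a macrophage marker, belongs instead to the monocyte and macrophage list, which was called higher. It averaged 40.8 ± 9.26 CPM in NC and 49.2 ± 18.9 with the conduit.

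Skeletal muscle genes were called higher with the conduit as a set and adipocyte genes lower, with an adjusted p of 0.872 for each with an estimated correlation. All 25 tested muscle genes were positive, with a median log2 fold change of 2.25 (camera adjusted p 3.3e-05, preset correlation). Acta1, the actin of skeletal muscle, stood at 5.87, 106 and 351 CPM in NC and at 20.8, 468 and 2095 with the conduit. All 17 adipocyte genes were negative, with a median of -1.01 (0.00059). Plin1, which coats fat droplets, stood at 298, 129 and 646 CPM in NC and at 110, 191 and 158 with the conduit. The muscle call ended without NC 1 (0.411) or implant 3 (0.265) and with haemoglobin as a covariate (0.669). Without NC 3 the adipocyte list changed direction (0.905), and with the covariate its adjusted p was 1.3e-11.

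The haemoglobin and red cell list was called higher by camera (adjusted p 0.00059), while its median log2 fold change was -0.22 and 8 of its 10 members were negative. The fold changes were fitted to counts, while camera tested log2 CPM. In mean log2 CPM relative to the 6 libraries, the list stood at -3.05, -2.87 and 2.91 in NC and at 0.27, 1.04 and 1.69 with the conduit. Its adjusted p was 0.872 with an estimated correlation, 0.278 without NC 1 and 0.247 without NC 2. The haemoglobin share averaged 9.13 ± 13.9% in NC and 11.9 ± 3.48% with the conduit (n = 3 each, two-sided exact permutation p 0.8, smallest possible 0.1). Ahsp, which encodes a chaperone of alpha haemoglobin, stood at 2.34, 2.66 and 290 CPM in NC and at 40.3, 77.3 and 113 with the conduit.

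Genes of the cell cycle rose as a set, with 25 of 27 positive and a median log2 fold change of 0.32 (camera adjusted p 0.00217 with the preset correlation, adjusted p = 0.872 with an estimated correlation). Relative to the mean of the 6 libraries, the list stood at -0.54, 0.41 and -0.36 log2 units in NC and at 0.75, -0.52 and 0.26 with the conduit, and the myelin list, at -2.27, 2.45 and -0.99 and at 1.39, -2.15 and 1.58, lay on the same side of the mean in each library. Mcm2, a part of the replicative helicase, averaged 16.5 ± 3.13 CPM in NC and 20.6 ± 1.27 with the conduit. Hypoxia and glycolysis genes rose as a set, with 18 of 25 positive and a median of 0.12 (0.0211, adjusted p = 0.872 with an estimated correlation). The list was lowest in NC 1 (-0.37 log2 units relative to the mean) and highest in implant 3 (0.35), as was the skeletal muscle list (-3.39 and 3.40). Slc16a3, a lactate exporter, averaged 4.22 ± 2.47 and 14.7 ± 7.98 CPM. Genes of cholesterol and fatty acid synthesis fell as a set, with 25 of 29 negative and a median of -0.16 (0.0211, adjusted p = 0.872 with an estimated correlation). Acaca, the first enzyme of fatty acid synthesis, averaged 203 ± 29.7 and 142 ± 20.0 CPM, and the lipogenic regulator Srebf1 averaged 235 ± 108 and 121 ± 34.1 CPM. Srebf1 stood at 233, 128 and 344 CPM in NC and at 82.2, 144 and 137 with the conduit. That is the same order of the 6 libraries as for the adipocyte gene Plin1. The list as a whole did not follow that order. In log2 units, it stood at -0.31, 0.59 and -0.05 in NC and at 0.28, -0.49 and -0.02 with the conduit. It was highest in NC 2, where the adipocyte list was lowest (-1.08) and the myelin list highest. It lay on the same side of the mean as the myelin list in each library except implant 3.

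The cell cycle call ended without NC 1 (0.411), NC 3 (0.058), implant 1 (0.899) or implant 3 (0.0501). That of hypoxia and glycolysis ended without NC 1 (0.695), NC 2 (0.548) or implant 3 (0.400), and that of cholesterol and fatty acid synthesis without NC 2 (0.780, with the direction changed) or implant 2 (0.874). With haemoglobin as a covariate, the adjusted p was 0.275 for hypoxia and glycolysis, with the direction changed, and 0.462 for cholesterol and fatty acid synthesis, while the cell cycle kept its call (0.00585).

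Matrix, vessel and other tissue lists were not called. Fibroblast and fibrous matrix genes had a median of -0.11 (camera adjusted p 0.0707), with Col1a1, a chain of type I collagen, at 3257 ± 702 CPM in NC and 3020 ± 749 with the conduit. Matrix proteases and inhibitors had a median of 0.03 (0.890). Endothelial genes had a median of 0.03 (0.281), with Pecam1 at 429 ± 242 and 437 ± 66.0 CPM. Pericyte and smooth muscle genes (0.00, 0.733), muscle regeneration genes (-0.07, 0.840), cartilage and bone genes (0.01, 0.733) and keratinocyte genes (0.21, 0.191) were not called either. The same held for oxidative phosphorylation (-0.06, 0.197), mitochondrially encoded genes (-0.14, 0.223), and immediate early and stress genes (-0.15, 0.231). Several of these passed without 1 library. On the higher side these were endothelial genes without NC 3 (5.3e-06) and keratinocyte genes without implant 3 (0.0442). On the lower side they were fibroblast genes without NC 2 (0.000143), implant 1 (0.0032) or implant 2 (0.000900), pericyte genes without implant 1 (0.0354), and endothelial genes without NC 2 (0.0191). Immediate early genes passed on the lower side without NC 1 (0.0066) or implant 1 (0.0224), and mitochondrially encoded genes without NC 1 (0.000348) or implant 2 (0.0240). Oxidative phosphorylation passed on the lower side without NC 1 (0.0044), NC 2 (0.0114) or implant 2 (0.0350), and on the higher side without NC 3 (0.00675). With the haemoglobin covariate endothelial (0.0240), oxidative phosphorylation (8.9e-09), mitochondrially encoded (0.0101) and immediate early genes (0.0013) passed on the lower side. Magnesium transport genes had a median of -0.01 (0.840), and the magnesium transporter Magt1 averaged 111 ± 6.76 CPM in NC and 99.7 ± 10.5 with the conduit.

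In all, camera with a preset correlation called 8 of 37 lists higher and 2 lower. No call held with an estimated correlation or in fry (smallest adjusted p 0.872 and 0.912), and each of the 10 calls ended when some single library was left out. The estimated correlation of the called lists ran from 0.12 (monocytes and macrophages) to 0.98 (haemoglobin), against the preset 0.01. Splits of the 6 libraries that cut across the groups called 8 to 26 lists, with a median of 15. Of the 27 lists not called, 18 passed when some single library was left out. The medians and means are of edgeR fold changes fitted to counts, while camera tested log2 CPM, so the 2 measures can differ in sign. The median, mean and camera direction differed in sign for 10 lists. Of these, haemoglobin was called, and the others were myelin, Schwann lineage identity, axon growth, B cells, pericytes, matrix proteases, muscle regeneration, cartilage and magnesium transport.

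**Figure D2:**
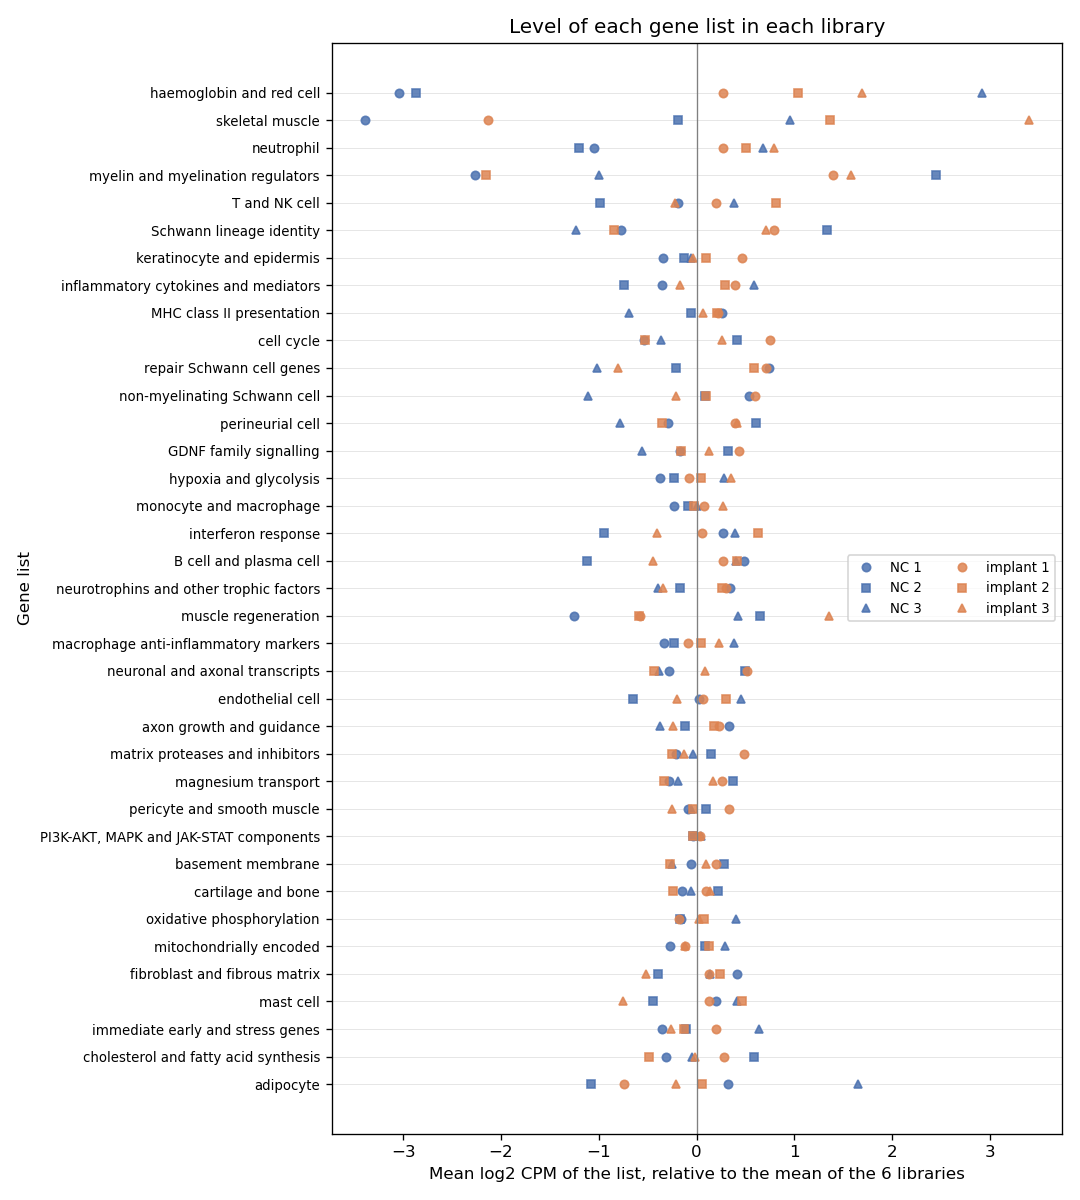
Mean log2 CPM of each of the 37 gene lists in each library, relative to the mean of the 6 libraries (horizontal axis, log2 units; blue for NC, orange for implant, marker shape for the library number). The myelin list spans 4.71 log2 units, with NC 1 and implant 2 lowest, and the muscle list is highest in implant 3.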

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

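The haemoglobin covariate and the removal of haemoglobin, muscle and adipocyte genes were chosen after seeing the data; the other alternatives were planned. The count of 0 genes per direction held under each scaling, filter and left-out library, the block and limma-voom, with 175 to 574 genes at an unadjusted p under 0.05 (1341 with the haemoglobin covariate). DESeq2 called 5 higher and 6 lower, and the cause was not tested. Of 126 named genes, 27 changed sign in some setting, as did 29 of 37 lists. The lists called higher numbered 8, and 6 to 11 with 1 library left out; those called lower numbered 2, and 1 to 6. With an estimated correlation or fry both counts were 0. The haemoglobin covariate gave 7 lists lower, and removing haemoglobin, muscle and adipocyte genes gave 1, since the adipocyte list was then not tested. With the covariate the direction changed for endothelial genes (adjusted p 0.0240), hypoxia and glycolysis (0.275) and haemoglobin (0.00496, as the covariate was built from these genes).

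With 1 library left out, 26 lists changed direction in some case, most with neither value past the threshold (myelin without NC 1, NC 3, implant 1 or implant 3, neurotrophins without NC 2, NC 3 or implant 1, and repair Schwann genes without NC 3, implant 1 or implant 2). Where either value was past it, the direction changed without NC 2 for cholesterol and fatty acid synthesis (adjusted p 0.780, range over the 6 libraries left out 5.5e-05 to 0.874) and endothelial genes (0.0191, range 5.3e-06 to 0.940). Without NC 3 it changed for adipocytes (0.905, range 2.8e-13 to 0.905) and oxidative phosphorylation (0.00675, range 0.00435 to 0.899). The cause was not tested.

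The replicate numbers did not pair the samples: correlations of deviations from the group means were 0.099, -0.718 and 0.055, and NC 1, NC 2 and NC 3 matched implant 2, 3 and 2 best. With the replicate block 0 genes were called (188 at an unadjusted p under 0.05, smallest adjusted p 0.760) and 8 lists higher and 2 lower.

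Spread between libraries limited the gene test, and depth was not varied: simulated genes changed 2-fold were recovered in 0 of 50 cases at the dispersion of these libraries, and in 95.9% at a dispersion of 0.01.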

Other observations

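Some trophic genes differed between libraries of one group by more than the groups differed. Artn, which encodes artemin of the GDNF family, stood at 2.75, 0.52 and 0.43 CPM in NC 1, NC 2 and NC 3 and at 1.00, 2.77 and 0.12 in implant 1, implant 2 and implant 3. Shh stood at 0.62, 22.5 and 2.39 CPM in NC and at 26.2, 0.38 and 3.66 with the conduit. Fosb, an immediate early gene, stood at 351 CPM in NC 3 and between 5.61 and 13.6 in the other 5 libraries. These genes, except Fosb, were named after their values were seen.

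The tests below were chosen after the results were seen, except the estimated correlation and the runs without 1 library, which were planned, and the bounds used to read them were set with related values already known. The bound on the standard error in the test of blood was added after its first result for T and NK cells. The real split called 0 genes, a count that all 10 splits of the 6 libraries into 3 and 3 reach by construction, so the comparison decides nothing, and the highest other gave 414. For lists, 9 splits, the real one included, gave at least the real 10. The 9 other splits called 8 to 26 lists, with a median of 15. With 10 splits no share can go under 0.05, so the splits cannot back the list calls. They do show that splits cutting across the groups mostly called as many lists or more. The split that set NC 1, NC 3 and implant 2 against NC 2, implant 1 and implant 3 gave the 414 genes, while 8 other splits gave 0, which points to a structure of the samples that the groups do not follow.

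Myelin transcripts differed widely between libraries of one group. Haemoglobin RNA taking counts is argued against, since the highest share, 25.2% in NC 3, could lower other genes by at most 0.42 log2 units where the myelin list spanned 4.71, and NC 1, with the lowest myelin level, had 1.19%. Fewer Schwann cells as the whole cause are argued against for NC 1 and implant 2. There the median of 14 other Schwann markers lay 2.22 ± 0.77 and 1.62 ± 0.38 log2 units (bootstrap SE) above that of the myelin genes. The bootstrap drew genes of 1 library as if they were independent. Its SE leaves out their correlation, estimated at 0.88 for the myelin list and 0.47 for lineage identity, and is too small to that extent. Relative to the mean of the 6 libraries, these markers stood at -0.14 in NC 1 and -0.65 in implant 2. Fewer Schwann cells may thus account for part of the drop in implant 2. The 14 include Postn, also a fibroblast list gene, which was higher where myelin was low. In NC 3 the other markers lay as low as myelin (-0.18 ± 0.38), so fewer Schwann cells may account for that library. An exchange of NC 2 and implant 2, which gives the 414 genes, cannot be told apart from a structure unrelated to the groups, because any such halving lies 1 exchange away; nerve segment and stage of regeneration were not tested.

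Skeletal muscle genes were called higher as a set with the conduit at camera's preset correlation only (adjusted p = 0.872 with an estimated correlation, 0.411 without NC 1 and 0.265 without implant 3). Muscle tissue carried into the samples is a candidate explanation: 21 of 25 genes followed the mean of the others over the 6 libraries with r above 0.9. Acta1, the most abundant of the named muscle genes, spanned 357-fold, up to 2095 CPM in implant 3. An effect of the conduit on muscle stays open and was not tested.

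Neutrophil and T cell genes were called higher as sets at camera's preset correlation only (adjusted p = 0.872 for both with an estimated correlation), and blood in the samples is a candidate explanation for part of the first, with an effect of the conduit open for both. The neutrophil difference was 1.05 ± 0.62 log2 units (SE) without and 0.29 ± 0.09 with haemoglobin as a covariate. The remaining difference was larger relative to its error, the camera call ended (adjusted p 0.361), and why it ended was not tested. NC 3, with the most haemoglobin, had a neutrophil level above that of the lowest implant library. For T and NK cells the difference went from 0.53 ± 0.50 to 0.13 ± 0.51, with no smaller error, so blood and an effect of the conduit cannot be told apart there with 6 libraries.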
